A study of Homo sapiens with 15 samples.

How the data were processed

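Polyadenylated RNA of cultured and sorted human erythroblasts was measured in 15 libraries, 3 for each of 5 stages. Per the labels, RNA was extracted with RNeasy Plus Mini kits, libraries were made with Illumina TruSeq reagents, and Bowtie, eXpress 1.2.0 and the hg19 build were used. The Bowtie version, the Ensembl release and the order of the steps are not given in the sources used here. Each library's deposited table lists the same 181648 Ensembl transcripts. Per the file headers, it gives an estimated count for each transcript, the expected count after eXpress divided reads shared between transcripts. The headers also name counts of reads that mapped to 1 transcript only and of all mapped reads, which the authors left unscaled. Further columns are an effective count and the effective length in bases. The deposited FPKM values were made by eXpress from the estimated count, the effective length and the library total. Libraries of replicate 1 held from 178970502 to 218273576 estimated counts and those of replicates 2 and 3 from 22582415 to 42305465.

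Estimated counts were summed by gene and rounded to whole numbers. Genes were assigned by transcript identifier from GENCODE release 29, whose coordinates are for GRCh38, so that it served for names, types and chromosomes and not for positions in hg19. It held 149817 of the transcripts (82.5%), with from 86.5% to 92.5% of a library's estimated counts, and 31831 transcripts had no gene and were left out. The 45625 genes were filtered with edgeR's filterByExpr by stage, which kept 14919. A library's floor, the CPM that 3 counts give, was 0.0934 ± 0.0677 CPM (SD, n = 3) on average in proE and 0.0697 ± 0.0497 CPM (SD, n = 3) in orthoE, and it covers counting error only.

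Tests were made in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Libraries were scaled with TMM, and 1 edgeR quasi-likelihood model (glmQLFit, glmQLFTest) with stage as the only term was fitted to all 15. The 5 stages were tested together by an F-test, and orthoE against proE and each adjacent pair of stages by contrasts. P-values were two-sided and adjusted by Benjamini-Hochberg, and a gene passed with an adjusted p under 0.05. Group means and SD are of TMM-scaled CPM, which can sum to more than the nominal total where the scaling factor is small. Folds are ratios of these means, and log2 fold changes with their SE come from the model. Shares of counts were compared with an exact two-sided permutation test, whose p cannot go below 0.1 for 3 against 3 libraries.

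There were 35 gene lists with 945 entries, of which 935 matched a gene, 12 by an older symbol. Lists with at least 5 measured genes, 33 in all, were tested with limma's camera at a preset correlation of 0.01 on log2 CPM and adjusted over the lists. The lymphocyte and the endothelial and stromal marker lists had fewer measured genes and were not tested. Camera was also run with an estimated correlation, and fry beside it. Transcript usage was tested for orthoE against proE and orthoE against polyE with edgeR's diffSpliceDGE on estimated counts of transcripts with at least 10 percent of their gene's mean count, in genes with several such transcripts, and a gene passed with an adjusted p under 0.05.

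The design, the lists, the tests, the other settings to try and the rule for naming genes were chosen before the data were examined. By that rule the text names the erythroid genes SLC4A1, ITGA4, GATA1, KLF1, HBB, HBA1, HBA2, HBG1, HBG2, ALAS2, TFRC, KIT, SF3B1 and EPB41, and the 10 largest rises and 10 largest falls for orthoE against proE, or 8 and 8 for adjacent stages. Those genes passed the test, had a mean of at least 50 CPM in the higher stage and no overlap between the 3 libraries of one stage and the 3 of the other. It also names members of a list from the 4 smallest adjusted p, and for usage the 8 smallest adjusted p among genes of at least 50 CPM with a transcript share moved by 20 points or more. Genes of the Y chromosome, XIST and features without a symbol were left out. Some results that the rule picks are not reported here.

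The shared number in sample titles was not stated to be a block. It was checked by correlating, across genes, the residuals of libraries with the same number in each pair of stages. The correlation was as low as 0.0675 for orthoE against proE and 0.0974 for orthoE against polyE. It was at least 0.435 for earlyBasoE against proE, 0.476 for lateBasoE against earlyBasoE and 0.287 for polyE against lateBasoE. For these the blocked count stands beside the main, stage-only one where it differed by more than 1.5-fold. Fits with a library left out were not blocked.

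Steps were tested on simulated negative binomial counts with these libraries' means, spread and depths and known changes. Changes of 1.5-fold, 2-fold, 4-fold and 8-fold, 50 genes each, were recovered in 0%, 6%, 54% and 76% of genes for orthoE against proE, 0%, 20%, 56% and 82% for earlyBasoE against proE, 0%, 14%, 60% and 76% for lateBasoE against earlyBasoE, 0%, 16%, 68% and 74% for polyE against lateBasoE and 0%, 8%, 50% and 68% for orthoE against polyE. The F-test over 5 stages recovered 2%, 22%, 80% and 86%. False calls were 4.23%, 7.06%, 1.32%, 4.82% and 5.97% of calls in these comparisons and 4.04% in the F-test, above 5% for earlyBasoE against proE and orthoE against polyE. A shifted list was called each time, with 0 others, but lists of correlated genes were not simulated. Usage changes of 2-fold, 4-fold, 8-fold, 16-fold and 64-fold, 40 genes each, were recovered in 5%, 15%, 32.5%, 45% and 82.5% of genes for orthoE against proE and 2.5%, 12.5%, 45%, 55% and 80% for orthoE against polyE, and 26.5% and 20.4% of the usage calls were false. Larger usage folds were added after a first run. Genes and transcripts were drawn independently, without shared reads.

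Other settings, fixed at the same time, were size factors by relative log expression (RLE), library size alone, removal of globin genes, no filter, uniquely mapped counts, the replicate number as a block, DESeq2, the 2 stages of a comparison alone, each library left out in turn, limma's diffSplice on voom values, transcripts from 5 percent of their gene's count, and the globin share of FPKM. Replicates 2 and 3 alone, and the globin share with the read-through gene, were chosen after seeing the data. Protein levels and cell counts were not analysed here.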

Results

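Polyadenylated RNA was sequenced from human erythroblasts that had been purified from cord blood, cultured and sorted by flow cytometry into 5 stages of terminal erythroid differentiation. The stages, in order of maturity, were proerythroblasts (proE), early basophilic (earlyBasoE), late basophilic (lateBasoE), polychromatic (polyE) and orthochromatic (orthoE) erythroblasts. Each stage had 3 libraries, called replicates 1, 2 and 3 here, for 15 in all. The labels do not say whether replicates were separate cultures or donors, so the p-values measure the spread between these samples. The 5 libraries of replicate 1 were sequenced without multiplexing per their labels. They held more estimated counts than replicates 2 and 3, a mean ratio of 6.26. Reads that mapped to 1 transcript alone made up from 11.6% to 15.8% of a library, and from 7.52% to 13.5% of the estimated counts lay in transcripts without a gene in the annotation. Of 45625 genes, 14919 were abundant enough to test. Between replicates of a stage, Spearman's rho across genes, which are not independent replicates, lay from 0.938 to 0.980. The first principal component held 63.5% of the variance and the second 11.2%. The comparisons ask which messages change from each stage to the next and between the ends of the series.

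Hemoglobin accumulates during these stages. The share of each library's estimated counts, those without a gene included, that fell on globin genes was 2.69% ± 0.205 (SD, n = 3) in proE, 4.37% ± 1.10 (SD, n = 3) in earlyBasoE, 8.66% ± 2.54 (SD, n = 3) in lateBasoE, 23.7% ± 1.38 (SD, n = 3) in polyE and 41.6% ± 1.98 (SD, n = 3) in orthoE. Between adjacent stages the share was higher in all 3 libraries of the later stage, with an exact two-sided permutation p of 0.1 each time, the smallest that 3 against 3 libraries can give. The alpha-globin genes HBA1 and HBA2 on chromosome 16 took 0.592% ± 0.0481 (SD, n = 3) of counts in proE and 21.97% ± 1.45 (SD, n = 3) in orthoE. The fetal gamma-globin genes HBG1 and HBG2 on chromosome 11 went from 1.64% ± 0.251 to 14.0% ± 0.967 (SD, n = 3), and beta-globin, HBB, from 0.404% ± 0.173 to 5.50% ± 1.19 (SD, n = 3). HBA1 and HBA2, like HBG1 and HBG2, are near-identical copies, so the division of reads within each pair is uncertain. A read-through gene that overlaps HBG2 took another 5.39% ± 1.10 (SD, n = 3) of orthoE counts and was not counted as globin. By uniquely mapped reads alone, the globin share was 0.712% ± 0.252 in proE and 10.2% ± 1.35 (SD, n = 3) in orthoE. By the deposited FPKM the direction was opposite, from 4.26% ± 0.728 to 0.774% ± 0.555 (SD, n = 3). Messages of the mitochondrial genome held 2.71% ± 0.423 (SD, n = 3) of counts in proE, 3.10% ± 0.280 in earlyBasoE, 2.67% ± 0.764 in lateBasoE, 0.942% ± 0.221 in polyE and 0.367% ± 0.0374 (SD, n = 3) in orthoE. The exact permutation p for that share was 0.1 for orthoE against proE, for polyE against lateBasoE and for orthoE against polyE, 0.3 for earlyBasoE against proE and 0.5 for lateBasoE against earlyBasoE.

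**Figure D1:**
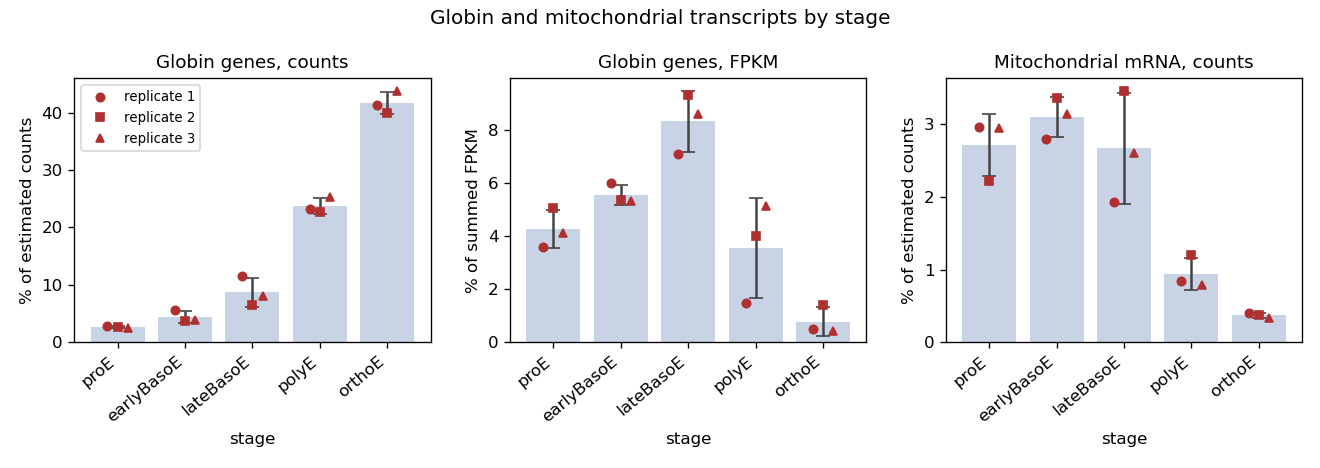
Percent of all estimated counts on globin genes, percent of the deposited FPKM on globin genes and percent of counts on mitochondrial messages (y axes) in the 5 stages (x axes); bars are means, error bars SD and points the 3 libraries of a stage. The globin share of counts is highest in orthoE, at 41.6% ± 1.98, where the globin share of FPKM is lowest, at 0.774% ± 0.555.

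Over the 5 stages together, 11539 of 14919 genes changed by the edgeR quasi-likelihood F-test (Benjamini-Hochberg adjusted p under 0.05), and 11774 had an unadjusted p under 0.05. Levels are mean CPM ± SD (n = 3), counts scaled to a common size by edgeR's trimmed mean of M-values (TMM). By TMM, the stages in order held the highest mean of 3675, 859, 1482, 1585 and 3938 changed genes. By library size peaks were not counted, but 8338 genes fell and 770 rose from polyE to orthoE. In stage order, SLC4A1, the anion exchanger band 3, had 906 ± 91.5, 3187 ± 1234, 9009 ± 2928, 24160.0000 ± 2706 and 30740.0000 ± 581 CPM. ALAS2, the first enzyme of erythroid heme synthesis, had 621 ± 8.02, 1106 ± 262, 2247 ± 717, 8534 ± 1301 and 23930.0000 ± 1237 CPM. KIT, the stem cell factor receptor, had 173 ± 26.7, 82.2 ± 9.53, 21.6 ± 3.76, 0.443 ± 0.165 and 1.29 ± 0.763 CPM, and MYB, a progenitor transcription factor, had 257 ± 52.3, 158 ± 24.9, 72.4 ± 9.32, 1.69 ± 0.664 and 2.34 ± 1.74 CPM. TFRC, the transferrin receptor, had 3848 ± 536, 5368 ± 1603, 6922 ± 2030.0000, 11180.0000 ± 2730.0000 and 5096 ± 444 CPM, highest in polyE by TMM but in lateBasoE by library size. SLC4A1 and ITGA4 encode antigens often used to sort these stages, by general knowledge and not per the labels, so their change is not independent of the sorting if they were used. TMM and library-size scaling differ for late stages. The median gene's log2 fold change was higher by TMM than by library size by 2.37 for orthoE against proE, 0.0909 for earlyBasoE against proE, 0.241 for lateBasoE against earlyBasoE, 0.820 for polyE against lateBasoE and 1.21 for orthoE against polyE. A rise smaller than these shifts is a fall as a share of counts, and such named genes carry their library-size value.

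**Figure D2:**
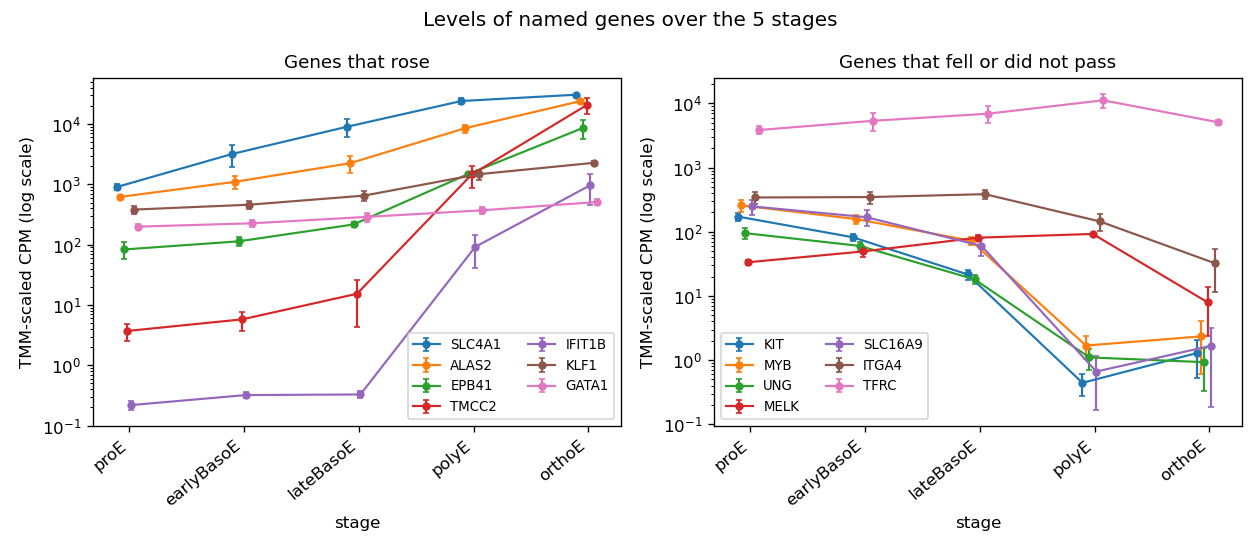
TMM-scaled CPM (y axes, log scale) over the 5 stages (x axes) for 7 genes with higher orthoE than proE levels and 7 others; points are means of 3 libraries and bars SD. By library size GATA1 is lower in orthoE than in proE (log2 fold change −1.03), as is TFRC (−1.97), while the other rises shown keep their direction.

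Between the ends of the series, orthochromatic cells are about to lose their nucleus and proerythroblasts are large dividing precursors. Levels here are mean CPM ± SD (n = 3 libraries per stage) and log2 fold changes are ± SE. Band 3 messages, SLC4A1 (30738 ± 581 against 906 ± 91.5 CPM, log2 fold change 5.08 ± 0.32, adjusted p = 8.7e-09), rose. So did ALAS2 (23931 ± 1237 against 621 ± 8.02 CPM, log2 fold change 5.27 ± 0.28, adjusted p = 2.3e-09) and the skeletal protein 4.1 gene EPB41 (8663 ± 3012 against 83.3 ± 26.3 CPM, log2 fold change 6.70 ± 0.34, adjusted p = 1.9e-09). The glucose transporter gene SLC2A1 rose 54.0-fold, the skeletal protein gene DMTN 36.2-fold and the mitochondrial iron importer SLC25A37 37.6-fold. KIT fell 133-fold (1.29 ± 0.763 against 173 ± 26.7 CPM, log2 fold change −7.03 ± 0.39, adjusted p = 3.2e-09) and MYB 109.9-fold (adjusted p = 4.6e-08). The erythroid regulators GATA1 (log2 fold change 1.36 ± 0.17, adjusted p = 6.8e-06) and KLF1 (log2 fold change 2.57 ± 0.21, adjusted p = 9.6e-08) rose by TMM, and by library size GATA1 was at −1.03 and KLF1 at 0.19. The splicing factor gene SF3B1 (log2 fold change 1.38 ± 0.27, adjusted p = 0.00042) likewise stood at −1.03 by library size. TFRC did not pass (log2 fold change 0.41 ± 0.26, adjusted p = 0.18) and was at −1.97 by library size, while it passed as higher in orthoE with RLE size factors, DESeq2, uniquely mapped counts, a replicate block or the 2 stages alone. The integrin gene ITGA4 was 10.54-fold lower. HBA1 rose 114-fold, HBA2 359-fold, HBG2 42.2-fold, HBB 68.5-fold (adjusted p = 4.9e-07), and HBG1 had a log2 fold change of 5.49 ± 0.80.

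The 10 largest rises among abundant genes were in messages of low level in proE, each higher in all 3 orthoE libraries than in any proE library. The neuronal adaptor gene RUNDC3A (2772 ± 179 against 0.442 ± 0.173 CPM, log2 fold change 12.74 ± 0.62) lies on chromosome 17. On chromosome 1 lies TMCC2 (20619 ± 6179 against 3.71 ± 1.15 CPM, log2 fold change 12.44 ± 0.74), and on chromosome 12 lies TCP11L2 (1851 ± 275 against 0.356 ± 0.226 CPM, log2 fold change 12.43 ± 0.92). The interferon-induced family member IFIT1B (964 ± 509 against 0.219 ± 0.0395 CPM, log2 fold change 12.19 ± 0.73) lies on chromosome 10. Heme oxygenase 1, HMOX1 (2238 ± 251 against 0.945 ± 0.546 CPM, log2 fold change 11.15 ± 0.48), lies on chromosome 22. For 5 more the proE level was near or at 0, so that no fold is given. They were OSR2 (53.0 ± 34.4 against 0 ± 0 CPM), DEPP1 (448 ± 29.4 against 0.0573 ± 0.0154 CPM) and KRT1 (225 ± 87.3 against 0.0244 ± 0.0266 CPM). OR2W3 (157 ± 138 against 0.0787 ± 0.136 CPM) and ASAP3 (105 ± 20.2 against 0.0335 ± 0.0303 CPM) completed them. Among the largest falls were EPCAM (log2 fold change −8.57 ± 0.90) on chromosome 2 and the monocarboxylate transporter family member SLC16A9 (1.67 ± 1.49 against 249 ± 66.3 CPM, log2 fold change −7.61 ± 0.96) on chromosome 10. MOB3B (log2 fold change −7.47 ± 0.69), the long noncoding RNA UCA1 (log2 fold change −7.39 ± 0.46) and the uracil-DNA glycosylase gene UNG (log2 fold change −7.03 ± 0.51) followed. KIT, FAM129B (log2 fold change −7.001 ± 0.37), FAM178B (log2 fold change −6.99 ± 0.76) and MYB were also among them. By the edgeR quasi-likelihood test, 10842 genes had a Benjamini-Hochberg adjusted p under 0.05, of which 4798 were higher and 6044 lower in orthoE. A change of at least 2-fold was found in 9536 of them, and 11157 genes had an unadjusted p under 0.05. By library size, 1358 genes were higher and 10812 lower. Replicates 2 and 3 alone, a comparison added after the data were seen, gave 10443 genes.

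**Figure D3:**
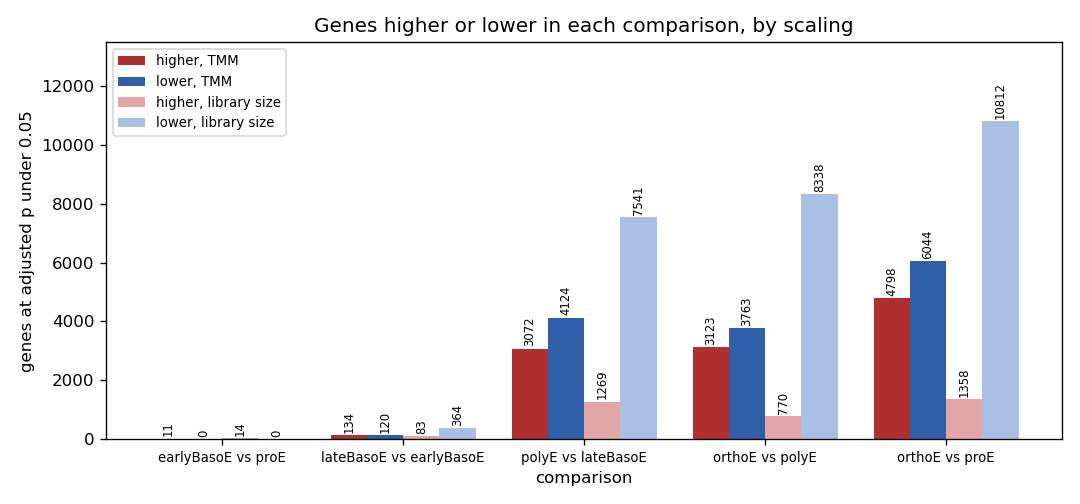
Number of genes (y axis) higher or lower in the first-named stage of each comparison (x axis) at an adjusted p under 0.05, by TMM and by library size. By TMM the orthoE against proE split is 4798 higher and 6044 lower, and by library size it is 1358 and 10812, and lower genes outnumber higher ones by library size in every comparison but earlyBasoE against proE, where none was lower.

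Maturing red cells are remodelled by proteolysis and autophagy. Gene lists for these and other processes, fixed before the data were examined, compared orthoE with proE. Of 30 genes of the ubiquitin system, 26 rose and 1 fell, with the same counts adjusted over the list alone and 17 and 8 by library size. The ubiquitin list had a median log2 fold change of 3.48 (1.07 by library size), adjusted p = 4.0e-09, and adjusted p = 0.16 with an estimated correlation. RNF10 rose 58.5-fold, UBXN6 61.5-fold and the ubiquitin ligase gene SIAH2 41.6-fold. Of 31 autophagy and mitophagy genes, 24 rose and 3 fell, with the same counts adjusted over the list alone and 16 and 13 by library size. The autophagy list had a median log2 fold change of 2.95 (0.55 by library size), adjusted p = 2.3e-07, and adjusted p = 0.078 with an estimated correlation. ATG14 rose 61.1-fold and GABARAPL2 27.9-fold. Of 37 red cell membrane genes, 32 rose and 2 fell, with the same counts adjusted over the list alone and 19 and 12 by library size. The membrane list had a median log2 fold change of 2.83 (0.42 by library size), adjusted p = 3.7e-09, and adjusted p = 0.23 with an estimated correlation. Of 11 globin and globin chaperone genes, 11 rose and 0 fell, with the same counts adjusted over the list alone and 8 and 0 by library size. The globin list had a median log2 fold change of 5.49 (3.13 by library size), adjusted p = 1.2e-06, and adjusted p = 0.078 with an estimated correlation. Of 17 heme synthesis genes, 10 rose and 3 fell, with the same counts adjusted over the list alone and 5 and 11 by library size. The heme list had a median log2 fold change of 1.13 (−1.27 by library size), adjusted p = 0.013, and adjusted p = 0.41 with an estimated correlation. Of 20 erythroid transcription factors, 11 rose and 6 fell, with 12 and 6 adjusted over the list alone and 8 and 11 by library size. The erythroid factor list had a median log2 fold change of 1.26 (−1.12 by library size), adjusted p = 0.025, and adjusted p = 0.41 with an estimated correlation. NFE2 rose 13.1-fold and FOXO3 78.0-fold. Of 21 cyclin-dependent kinase inhibitors and cell cycle exit genes, 15 rose and 3 fell, with 16 and 3 adjusted over the list alone and 10 and 9 by library size. The kinase inhibitor list had a median log2 fold change of 2.65 (0.27 by library size), adjusted p = 0.00062, and adjusted p = 0.078 with an estimated correlation. Of 21 translation control genes, 16 rose and 4 fell, with the same counts adjusted over the list alone and 7 and 10 by library size. The translation control list had a median log2 fold change of 2.24 (−0.15 by library size), adjusted p = 0.0015, and adjusted p = 0.23 with an estimated correlation. Of 26 antioxidant genes, 19 rose and 4 fell, with the same counts adjusted over the list alone and 5 and 13 by library size. The antioxidant list had a median log2 fold change of 1.48 (−0.88 by library size), adjusted p = 0.0015, and adjusted p = 0.23 with an estimated correlation. Of 20 genes of erythropoietin and stem cell factor signalling, 11 rose and 6 fell, with 12 and 6 adjusted over the list alone and 5 and 11 by library size. The signalling list had a median log2 fold change of 1.54 (−0.84 by library size), adjusted p = 0.050, and adjusted p = 0.41 with an estimated correlation. Of 19 replication-dependent histone genes, 14 rose and 1 fell, with 15 and 1 adjusted over the list alone and 8 and 4 by library size. The histone list had a median log2 fold change of 3.92 (1.52 by library size), adjusted p = 0.00014, and adjusted p = 0.31 with an estimated correlation. HIST1H2AC rose 109.9-fold. Only polyadenylated histone RNA was measured. Several genes are near-identical copies with uncertain division of reads.

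In the following lists more genes fell than rose in orthoE. Of 39 ribosome biogenesis genes, 2 rose and 36 fell, with the same counts adjusted over the list alone and 0 and 39 by library size. The ribosome biogenesis list had a median log2 fold change of −2.94, adjusted p = 3.7e-09, and adjusted p = 0.078 with an estimated correlation. NOLC1 fell 10.7-fold and NOP14 10.1-fold. Of 70 ribosomal protein genes, 0 rose and 61 fell, with 0 and 62 adjusted over the list alone and 0 and 70 by library size. The ribosomal protein list had a median log2 fold change of −1.61, adjusted p = 1.6e-08, and adjusted p = 0.48 with an estimated correlation. RPL3 fell 8.505-fold and RPL10A 14.3-fold, and both share reads with pseudogenes. Of 41 DNA replication genes, 2 rose and 35 fell, with 2 and 37 adjusted over the list alone and 0 and 41 by library size. The replication list had a median log2 fold change of −3.04, adjusted p = 4.3e-08, and adjusted p = 0.39 with an estimated correlation. PCNA fell 9.16-fold and GINS2 17.0-fold. Of 24 genes of serine, one-carbon and nucleotide synthesis, 1 rose and 22 fell, with the same counts adjusted over the list alone and 0 and 24 by library size. The serine list had a median log2 fold change of −3.23, adjusted p = 1.1e-05, and adjusted p = 0.078 with an estimated correlation. Of 35 mitochondrial translation genes, 0 rose and 32 fell, with the same counts adjusted over the list alone and 0 and 35 by library size. The mitochondrial translation list had a median log2 fold change of −2.10, adjusted p = 4.4e-08, and adjusted p = 0.14 with an estimated correlation. MRPS27 fell 10.4-fold and MRPL3 13.0-fold. Of 31 nuclear export and import genes, 7 rose and 23 fell, with the same counts adjusted over the list alone and 2 and 27 by library size. The nuclear transport list had a median log2 fold change of −2.14, adjusted p = 0.0055, and adjusted p = 0.41 with an estimated correlation. Of 48 nuclear genes of oxidative phosphorylation, 10 rose and 27 fell, with the same counts adjusted over the list alone and 0 and 48 by library size. The oxidative phosphorylation list had a median log2 fold change of −0.73, adjusted p = 0.023, and adjusted p = 0.60 with an estimated correlation. Of 13 genes of the mitochondrial genome, 0 rose and 12 fell, with the same counts adjusted over the list alone and 0 and 13 by library size. The mitochondrial genome list had a median log2 fold change of −1.34, adjusted p = 0.023, and adjusted p = 0.61 with an estimated correlation.

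Other lists did not pass for orthoE against proE. Chaperones gave 11 higher and 12 lower of 27 genes (12 and 12 adjusted over the list alone, 5 and 19 by library size), a median of 0.16 (−2.20 by library size) and adjusted p = 0.61. Cholesterol synthesis gave 6 higher and 8 lower of 24 genes (6 and 8 adjusted over the list alone, 2 and 22 by library size), a median of −0.21 (−2.60 by library size) and adjusted p = 0.64. Glycolysis and red cell enzymes gave 4 higher and 13 lower of 22 genes (4 and 13 adjusted over the list alone, 3 and 17 by library size), a median of −1.08 (−3.46 by library size) and adjusted p = 0.23. Iron handling gave 7 higher and 5 lower of 15 genes (7 and 5 adjusted over the list alone, 4 and 10 by library size), a median of 0.41 (−1.97 by library size) and adjusted p = 0.16. Mitosis gave 4 higher and 19 lower of 38 genes (4 and 18 adjusted over the list alone, 0 and 38 by library size), a median of −0.84 (−3.26 by library size) and adjusted p = 0.11. Progenitor genes gave 2 higher and 10 lower of 16 genes (2 and 10 adjusted over the list alone, 1 and 13 by library size), a median of −2.16 (−4.53 by library size) and adjusted p = 0.069. Splicing factors gave 12 higher and 28 lower of 51 genes (12 and 28 adjusted over the list alone, 4 and 44 by library size), a median of −0.85 (−3.25 by library size) and adjusted p = 0.36. Median, mean and test differed in sign for 3 of them. Chromatin condensation and enucleation gave 11 higher and 17 lower of 35 genes (11 and 17 adjusted over the list alone, 5 and 29 by library size), a median of −0.54 (−2.95 by library size), a mean of 0.16 and adjusted p = 0.84, with a test that pointed down. Nonsense-mediated decay gave 6 higher and 6 lower of 17 genes (6 and 6 adjusted over the list alone, 0 and 17 by library size), a median of −0.31 (−2.65 by library size), a mean of −0.06 and adjusted p = 0.84, with a test that pointed up. The proteasome core gave 11 higher and 10 lower of 29 genes (11 and 10 adjusted over the list alone, 0 and 28 by library size), a median of 0.08 (−2.30 by library size), a mean of −0.03 and adjusted p = 0.63, with a test that pointed up. Markers of other cell types were measured too. Of 12 megakaryocyte and platelet markers, 9 rose and 0 fell, with the same counts adjusted over the list alone and 6 and 1 by library size. The megakaryocyte list had a median log2 fold change of 3.76 (1.40 by library size), adjusted p = 0.0015, and adjusted p = 0.39 with an estimated correlation. TUBB1 rose 13.6-fold (98.0 ± 35.6 against 7.20 ± 0.463 CPM, n = 3). Of 14 monocyte and macrophage markers, 10 rose and 0 fell, with the same counts adjusted over the list alone and 1 and 3 by library size. The monocyte list had a median log2 fold change of 1.89 (−0.47 by library size), adjusted p = 0.031, and adjusted p = 0.60 with an estimated correlation. Of 11 granulocyte markers, 3 rose and 0 fell, with 2 and 0 adjusted over the list alone and 0 and 2 by library size. The granulocyte list had a median log2 fold change of 1.71 (−0.58 by library size), adjusted p = 0.34. Of 9 mast cell, eosinophil and basophil markers, 0 rose and 4 fell, with 0 and 3 adjusted over the list alone and 0 and 8 by library size. The mast cell list had a median log2 fold change of −1.64, adjusted p = 0.37. KIT is among the last. Camera, limma's list test with a preset correlation, called 21 of 33 lists, and none of these calls held with an estimated correlation. The list p-values thus rest on the preset correlation, and the counts of rises and falls within a list depend on the scaling. Other splits of the same 6 libraries called up to 20 lists but kept part of the stage difference, so they decide nothing.

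**Figure D4:**
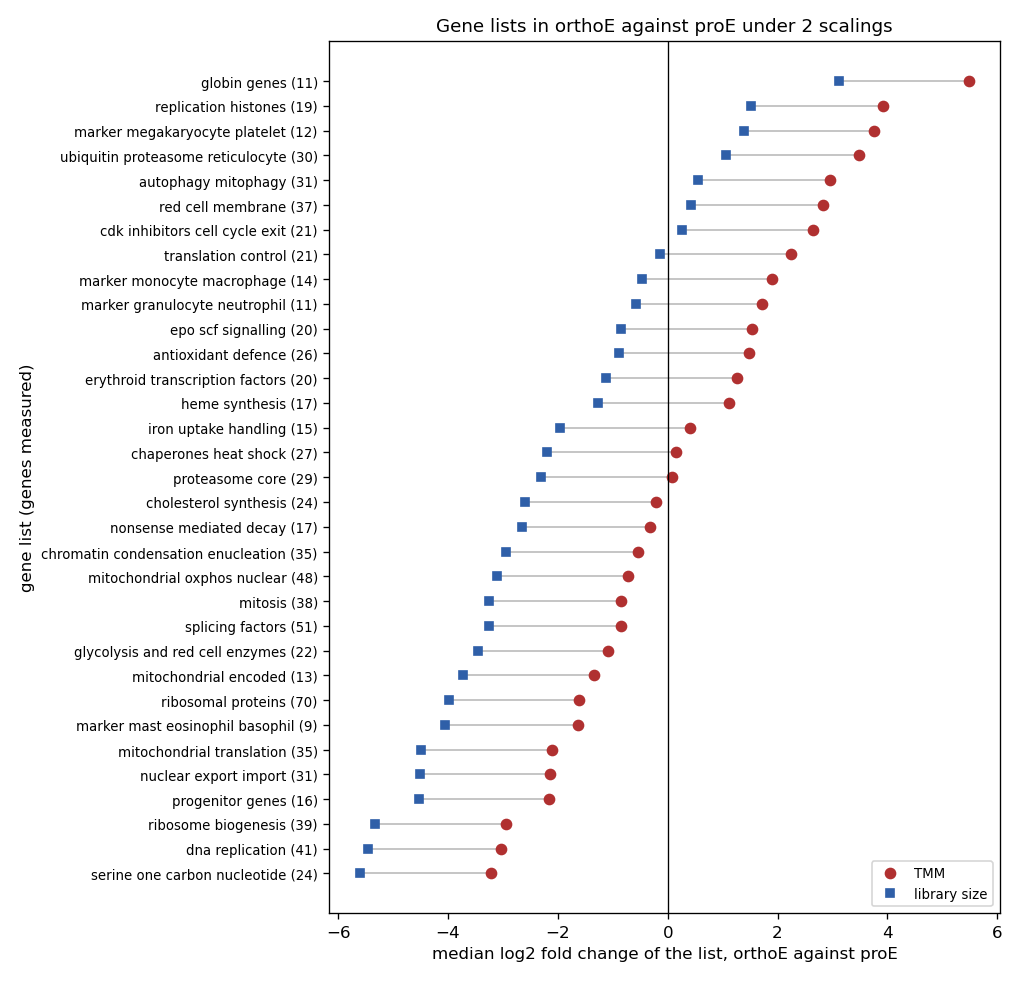
Median log2 fold change of orthoE against proE (x axis) for 33 gene lists (y axis), by TMM and by library size. Medians by library size lie below those by TMM, and lists such as heme synthesis (1.13 by TMM, −1.27 by library size) change sign between the scalings.

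From proE to earlyBasoE, cells extend their erythroid program while they go on dividing. Levels are mean CPM ± SD (n = 3) and log2 fold changes ± SE. Band 3, SLC4A1 (3187 ± 1234 against 906 ± 91.5 CPM, log2 fold change 1.81 ± 0.27, adjusted p = 0.025), rose, and so did the minor alpha-like globin gene HBM (76.2 ± 9.88 against 15.9 ± 2.67 CPM, log2 fold change 2.27 ± 0.26, adjusted p = 0.0039). Acetylcholinesterase, ACHE (65.8 ± 5.88 against 27.4 ± 4.63 CPM, log2 fold change 1.26 ± 0.15, adjusted p = 0.0058), and the focal adhesion gene TNS1 (131 ± 79.98 against 19.9 ± 0.771 CPM, log2 fold change 2.72 ± 0.39, adjusted p = 0.021) rose too. ALAS2 (0.83 ± 0.23, adjusted p = 0.32) and HBA1 (1.31 ± 0.28, adjusted p = 0.14) did not pass. Nor did KIT (−1.07 ± 0.29, adjusted p = 0.29) or the proliferation marker MKI67 (1.07 ± 0.36, adjusted p = 0.55). SLC25A37 (1.06 ± 0.23, adjusted p = 0.17) did not pass either, but passed with the replicate number as a block (adjusted p = 0.0079) and with DESeq2. The edgeR quasi-likelihood test called 11 genes, 11 higher and 0 lower in earlyBasoE, with 909 at an unadjusted p under 0.05. By library size 14 were higher and 0 lower, and DESeq2 called 111 higher and 58 lower, among them 4 of the genes named here that did not pass by edgeR. Libraries with the same replicate number moved together between these stages, and with that number as a block 99 genes passed, 72 higher and 27 lower. Unblocked, the count fell to 1 without proE replicate 1 and to 5 without proE replicate 2. It was 4 without proE replicate 3 or earlyBasoE replicate 1. It was 20 without earlyBasoE replicate 3. SLC4A1 (adjusted p from 0.13 to 0.15) and TNS1 (adjusted p from 0.12 to 0.15) did not pass without any 1 of the 3 proE libraries. Without earlyBasoE replicate 1 SLC4A1 had adjusted p = 0.079. Without proE replicate 1 HBM had adjusted p = 0.055 and ACHE adjusted p = 0.076. Replicates 2 and 3 alone gave 8 genes.

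By camera, erythroid lists shifted from proE to earlyBasoE although few of their genes passed alone. Of 37 red cell membrane genes, 1 rose and 0 fell, with 12 and 0 adjusted over the list alone and 1 and 0 by library size. The membrane list had a median log2 fold change of 0.49, adjusted p = 6.8e-13, and adjusted p = 0.18 with an estimated correlation. Of 11 globin and globin chaperone genes, 1 rose and 0 fell, with 3 and 0 adjusted over the list alone and 1 and 0 by library size. The globin list had a median log2 fold change of 0.67, adjusted p = 2.5e-07, and adjusted p = 0.18 with an estimated correlation. Of 17 heme synthesis genes, 0 rose and 0 fell, with 3 and 0 adjusted over the list alone and 0 and 0 by library size. The heme list had a median log2 fold change of 0.32, adjusted p = 2.5e-07, and adjusted p = 0.18 with an estimated correlation. Of 20 erythroid transcription factors, 0 rose and 0 fell, with 3 and 0 adjusted over the list alone and 0 and 0 by library size. The erythroid factor list had a median log2 fold change of 0.28, adjusted p = 2.6e-06, and adjusted p = 0.18 with an estimated correlation. Of 38 mitosis genes, 0 rose and 0 fell, with the same counts adjusted over the list alone and 0 and 0 by library size. The mitosis list had a median log2 fold change of 0.58, adjusted p = 8.5e-10, and adjusted p = 0.45 with an estimated correlation. Of 16 progenitor genes, 0 rose and 0 fell, with 0 and 2 adjusted over the list alone and 0 and 0 by library size. The progenitor list had a median log2 fold change of −0.54, adjusted p = 0.00068, and adjusted p = 0.18 with an estimated correlation. Of the 4 marker lists of other cell types, 3 shifted upward too. Of 11 granulocyte markers, 0 rose and 0 fell, with the same counts adjusted over the list alone and 0 and 0 by library size. The granulocyte list had a median log2 fold change of 1.16, adjusted p = 0.0011, and adjusted p = 0.25 with an estimated correlation. Of 14 monocyte and macrophage markers, 0 rose and 0 fell, with the same counts adjusted over the list alone and 0 and 0 by library size. The monocyte list had a median log2 fold change of 1.12, adjusted p = 0.00027, and adjusted p = 0.40 with an estimated correlation. Of 12 megakaryocyte and platelet markers, 0 rose and 0 fell, with the same counts adjusted over the list alone and 0 and 0 by library size. The megakaryocyte list had a median log2 fold change of 0.66, adjusted p = 0.031, 0.059 with the block and 0.55 with an estimated correlation. Of 9 mast cell, eosinophil and basophil markers, 0 rose and 0 fell, with 0 and 1 adjusted over the list alone and 0 and 0 by library size. The mast cell list had a median log2 fold change of 0.34, adjusted p = 0.77. In all, 20 lists were called, and none with an estimated correlation. By fry, which asks whether the genes of a list move 1 way on balance, the globin list alone passed (adjusted p = 0.039).

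Between earlyBasoE and lateBasoE, cells shrink, hemoglobin synthesis gains pace and the progenitor program recedes. Levels are mean CPM ± SD (n = 3) and log2 fold changes ± SE. Band 3, SLC4A1 (9009 ± 2928 against 3187 ± 1234 CPM, log2 fold change 1.499 ± 0.27, adjusted p = 0.020), and ALAS2 (2247 ± 717 against 1106 ± 262 CPM, log2 fold change 1.02 ± 0.23, adjusted p = 0.043) rose. HBM (log2 fold change 2.06 ± 0.25), HBA2 (log2 fold change 1.99 ± 0.39) and TNS1 (log2 fold change 2.18 ± 0.38) rose as well. Other rises were in the erythroid transcription factor gene SOX6 (85.8 ± 18.1 against 23.4 ± 6.39 CPM, log2 fold change 1.87 ± 0.38, adjusted p = 0.033), the linker histone gene H1F0 (log2 fold change 1.78 ± 0.29) and the water channel gene AQP3 (log2 fold change 1.76 ± 0.21). PAQR9 (log2 fold change 2.05 ± 0.42) and MXD3 (log2 fold change 1.78 ± 0.39) completed the 8 largest. Cell cycle genes that rose were CCND3 (log2 fold change 1.35 ± 0.27, adjusted p = 0.029), CDC25B (log2 fold change 1.53 ± 0.33, adjusted p = 0.037) and CDC25C (log2 fold change 1.49 ± 0.31, adjusted p = 0.035). The stem cell factor receptor gene KIT (21.6 ± 3.76 against 82.2 ± 9.53 CPM, log2 fold change −1.92 ± 0.29, adjusted p = 0.013) fell, and so did CDK6 (log2 fold change −1.15 ± 0.23, adjusted p = 0.030). DDN (log2 fold change −2.17 ± 0.40), UNG (log2 fold change −1.73 ± 0.37), SLC26A2 (log2 fold change −1.499 ± 0.26) and the glycolytic gene GPI (log2 fold change −1.39 ± 0.26) fell. FAM129B (log2 fold change −1.35 ± 0.27), SEMA4C (log2 fold change −1.31 ± 0.30) and ANKRD27 (log2 fold change −1.16 ± 0.26) completed the 8 largest falls. GYPB (log2 fold change 1.01 ± 0.17) rose. The edgeR quasi-likelihood test called 254 genes, 134 higher and 120 lower in lateBasoE, 176 of them by at least 2-fold, with 2361 at an unadjusted p under 0.05. By library size 83 were higher and 364 lower. With the replicate number as a block, 1439 genes passed, 784 higher and 655 lower, all 254 among them. Unblocked, the count depended on single libraries. It was 0 without earlyBasoE replicate 2 (1924 at an unadjusted p under 0.05) and 0 without earlyBasoE replicate 3 (1658), so none of the genes named here passed then, whereas DESeq2 on all libraries called 1117. It was 1 without lateBasoE replicate 1, 23 without lateBasoE replicate 3 and 154 without lateBasoE replicate 2. Replicates 2 and 3 alone gave 422 genes, 278 higher and 144 lower.

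Among lists, mitotic and erythroid genes shifted upward from earlyBasoE to lateBasoE and ribosome assembly downward. Of 38 mitosis genes, 2 rose and 0 fell, with 32 and 0 adjusted over the list alone and 2 and 0 by library size. The mitosis list had a median log2 fold change of 1.03, adjusted p = 1.7e-16, and adjusted p = 0.26 with an estimated correlation. Of 37 red cell membrane genes, 4 rose and 0 fell, with 22 and 0 adjusted over the list alone and 4 and 0 by library size. The membrane list had a median log2 fold change of 0.78, adjusted p = 3.7e-16, and adjusted p = 0.10 with an estimated correlation. Of 11 globin and globin chaperone genes, 2 rose and 0 fell, with 8 and 0 adjusted over the list alone and 3 and 0 by library size. The globin list had a median log2 fold change of 1.12, adjusted p = 1.3e-08, and adjusted p = 0.049 with an estimated correlation. Of 17 heme synthesis genes, 2 rose and 0 fell, with 11 and 0 adjusted over the list alone and 1 and 0 by library size. The heme list had a median log2 fold change of 0.72, adjusted p = 6.0e-09, and adjusted p = 0.10 with an estimated correlation. Of 21 cyclin-dependent kinase inhibitors and cell cycle exit genes, 2 rose and 0 fell, with 9 and 1 adjusted over the list alone and 3 and 0 by library size. The kinase inhibitor list had a median log2 fold change of 0.80, adjusted p = 3.7e-05, and adjusted p = 0.049 with an estimated correlation. Of 39 ribosome biogenesis genes, 0 rose and 7 fell, with 0 and 20 adjusted over the list alone and 0 and 11 by library size. The ribosome biogenesis list had a median log2 fold change of −0.55, adjusted p = 2.1e-15, and adjusted p = 0.033 with an estimated correlation. Examples that fell were NOLC1 (log2 fold change −0.79 ± 0.15) and GNL3 (log2 fold change −0.90 ± 0.17). Of 16 progenitor genes, 0 rose and 3 fell, with 0 and 8 adjusted over the list alone and 0 and 5 by library size. The progenitor list had a median log2 fold change of −0.74, adjusted p = 0.00019, and adjusted p = 0.12 with an estimated correlation. The antioxidant list had a median of −0.02 and a mean of 0.12 and did not pass. In all, 17 lists were called. The ribosome biogenesis, globin and kinase inhibitor calls held with an estimated correlation.

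From lateBasoE to polyE the nucleus condenses and the cytoplasm fills with hemoglobin. Levels are mean CPM ± SD (n = 3) and log2 fold changes ± SE. The largest rise was in IFIT1B (92.1 ± 51.7 against 0.328 ± 0.0398 CPM, log2 fold change 8.15 ± 0.63, adjusted p = 4.4e-07). The hypoxia-inducible factor gene EPAS1 (81.7 ± 17.6 against 0.359 ± 0.264 CPM, log2 fold change 7.63 ± 0.65, adjusted p = 9.9e-07) and TMCC2 (1466 ± 582 against 15.3 ± 11.1 CPM, log2 fold change 6.57 ± 0.59) rose. TCP11L2 (log2 fold change 6.30 ± 0.71), ABLIM1 (log2 fold change 8.01 ± 0.93), arginase 1, ARG1 (log2 fold change 7.22 ± 0.68), the phagocytic receptor gene MERTK (log2 fold change 6.998 ± 0.50) and PLCL2 (log2 fold change 6.94 ± 0.93) completed the 8 largest. Among the 8 largest falls were S100A6 (4.21 ± 1.62 against 354 ± 44.9 CPM, log2 fold change −6.41 ± 0.26, adjusted p = 9.9e-09) and the transforming growth factor co-receptor gene ENG (2.50 ± 1.12 against 206 ± 12.9 CPM, log2 fold change −6.37 ± 0.57). SLC16A9 (log2 fold change −6.75 ± 0.92), SYNGR1 (log2 fold change −6.68 ± 0.68) and FAM178B (log2 fold change −6.42 ± 0.74) fell. So did RPS6KL1 (log2 fold change −5.77 ± 0.36), ACSBG1 (log2 fold change −5.44 ± 0.45) and MYB, the last by 42.9-fold. KIT fell 48.8-fold, RUNX1 5.23-fold and the GATA1 partner gene LDB1 4.13-fold. FOXO3 rose 9.74-fold, EPB41 6.88-fold and CD44 4.40-fold. The transferrin receptor gene TFRC (11185 ± 2730.5 against 6922 ± 2030.1 CPM, log2 fold change 0.69 ± 0.26, adjusted p = 0.044) rose by TMM and was at −0.12 by library size. TFRC did not pass without lateBasoE replicate 2 (adjusted p = 0.13), lateBasoE replicate 3 (adjusted p = 0.19), polyE replicate 1 (adjusted p = 0.19) or polyE replicate 2 (adjusted p = 0.069). The edgeR quasi-likelihood test called 7196 genes, 3072 higher and 4124 lower in polyE, 5386 of them by at least 2-fold, with 8110 at an unadjusted p under 0.05. By library size 1269 were higher and 7541 lower. Replicates 2 and 3 alone gave 7354.

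Ribosome lists shifted downward and clearance lists upward from lateBasoE to polyE. Of 39 ribosome biogenesis genes, 0 rose and 36 fell, with 1 and 36 adjusted over the list alone and 0 and 38 by library size. The ribosome biogenesis list had a median log2 fold change of −2.21, adjusted p = 2.1e-16, and adjusted p = 0.024 with an estimated correlation. NOP14 fell 8.18-fold and RRP9 31.3-fold. Of 35 mitochondrial translation genes, 0 rose and 33 fell, with 0 and 34 adjusted over the list alone and 0 and 35 by library size. The mitochondrial translation list had a median log2 fold change of −1.301, adjusted p = 9.2e-11, and adjusted p = 0.11 with an estimated correlation. Of 70 ribosomal protein genes, 0 rose and 50 fell, with 0 and 59 adjusted over the list alone and 0 and 69 by library size. The ribosomal protein list had a median log2 fold change of −0.85, adjusted p = 6.4e-09, and adjusted p = 0.43 with an estimated correlation. RPL23 fell 4.46-fold. Of 21 translation control genes, 11 rose and 4 fell, with 13 and 4 adjusted over the list alone and 7 and 6 by library size. The translation control list had a median log2 fold change of 0.84 (0.02 by library size), adjusted p = 0.016, and adjusted p = 0.36 with an estimated correlation. Of 24 genes of serine, one-carbon and nucleotide synthesis, 1 rose and 19 fell, with 2 and 19 adjusted over the list alone and 0 and 21 by library size. The serine list had a median log2 fold change of −1.60, adjusted p = 1.7e-06, and adjusted p = 0.10 with an estimated correlation. Of 41 DNA replication genes, 2 rose and 29 fell, with 2 and 31 adjusted over the list alone and 0 and 37 by library size. The replication list had a median log2 fold change of −0.96, adjusted p = 7.9e-05, and adjusted p = 0.43 with an estimated correlation. Of 13 genes of the mitochondrial genome, 0 rose and 12 fell, with the same counts adjusted over the list alone and 0 and 13 by library size. The mitochondrial genome list had a median log2 fold change of −1.12, adjusted p = 0.0017, and adjusted p = 0.43 with an estimated correlation. MT-CO2 fell 2.37-fold. Of 30 genes of the ubiquitin system, 23 rose and 1 fell, with 24 and 1 adjusted over the list alone and 15 and 3 by library size. The ubiquitin list had a median log2 fold change of 1.298 (0.49 by library size), adjusted p = 6.4e-09, and adjusted p = 0.18 with an estimated correlation. UBE2H rose 23.6-fold and SIAH2 10.4-fold. Of 31 autophagy and mitophagy genes, 21 rose and 2 fell, with 22 and 2 adjusted over the list alone and 12 and 7 by library size. The autophagy list had a median log2 fold change of 1.18 (0.36 by library size), adjusted p = 4.5e-07, and adjusted p = 0.11 with an estimated correlation. The mitophagy receptor gene BNIP3L rose 8.63-fold and ATG14 9.02-fold. Of 37 red cell membrane genes, 28 rose and 2 fell, with 31 and 2 adjusted over the list alone and 17 and 3 by library size. The membrane list had a median log2 fold change of 1.31 (0.49 by library size), adjusted p = 1.1e-08, and adjusted p = 0.30 with an estimated correlation. Of 11 globin and globin chaperone genes, 10 rose and 0 fell, with the same counts adjusted over the list alone and 7 and 1 by library size. The globin list had a median log2 fold change of 1.86 (1.11 by library size), adjusted p = 6.3e-05, and adjusted p = 0.16 with an estimated correlation. Of 38 mitosis genes, 1 rose and 2 fell, with 0 and 2 adjusted over the list alone and 0 and 20 by library size. The mitosis list had a median log2 fold change of −0.03, adjusted p = 0.86. Of 9 mast cell, eosinophil and basophil markers, 0 rose and 5 fell, with the same counts adjusted over the list alone and 0 and 7 by library size. The mast cell list had a median log2 fold change of −3.39, adjusted p = 0.037, and adjusted p = 0.32 with an estimated correlation. In all, 21 lists were called, and ribosome biogenesis alone held with an estimated correlation.

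From polyE to orthoE, cells leave the cell cycle and prepare to expel the nucleus. Levels are mean CPM ± SD (n = 3) and log2 fold changes ± SE. The largest rise was in heme oxygenase 1, HMOX1 (2238 ± 251 against 19.5 ± 6.18 CPM, log2 fold change 6.84 ± 0.40, adjusted p = 2.2e-07). The Notch regulator gene NRARP (log2 fold change 6.81 ± 0.84), the calcium channel gene TRPV2 (848 ± 160.1 against 9.58 ± 5.57 CPM, log2 fold change 6.48 ± 0.42) and OSR2 (log2 fold change 6.40 ± 0.76) followed. BIRC3 (log2 fold change 5.96 ± 0.83), the FOXO target DEPP1 (log2 fold change 5.89 ± 0.60), IRF2BPL (log2 fold change 5.34 ± 0.56) and SP6 (log2 fold change 5.27 ± 0.61) completed the 8 largest. The largest falls were in genes of replication, repair and division. They were MELK (7.96 ± 5.61 against 92.5 ± 2.64 CPM, log2 fold change −3.60 ± 0.52, adjusted p = 8.4e-05), POLQ (log2 fold change −3.36 ± 0.35), CDCA4 (log2 fold change −3.35 ± 0.34) and BRCA1 (10.97 ± 6.005 against 109 ± 21.4 CPM, log2 fold change −3.34 ± 0.34). ARHGAP33 (log2 fold change −3.29 ± 0.50), UBR7 (log2 fold change −3.28 ± 0.38), HAUS8 (log2 fold change −3.28 ± 0.25) and STMN1 (39.8 ± 6.95 against 382 ± 94.6 CPM, log2 fold change −3.27 ± 0.21) completed the 8. TOP2A fell 8.32-fold, PRC1 8.05-fold, PCNA 5.30-fold and CCNA2 3.9996-fold. The linker histone gene HIST1H1C (1061 ± 148 against 34.8 ± 2.05 CPM, log2 fold change 4.93 ± 0.39, adjusted p = 1.0e-06) rose, as did the lamin gene LMNA (log2 fold change 2.31 ± 0.20). The bisphosphoglycerate synthesis gene BPGM (5432 ± 2349.6 against 826 ± 187 CPM, log2 fold change 2.72 ± 0.32), EPB41 (log2 fold change 2.54 ± 0.28) and glutathione peroxidase 1, GPX1 (log2 fold change 2.96 ± 0.28), also rose. The transferrin receptor gene TFRC (5096 ± 444 against 11185 ± 2730.5 CPM, log2 fold change −1.13 ± 0.27, adjusted p = 0.0032) fell. KLF1 (log2 fold change 0.63 ± 0.20, adjusted p = 0.018) rose by TMM and was at −0.60 by library size. It did not pass without polyE replicate 2 (adjusted p = 0.10), orthoE replicate 2 (adjusted p = 0.05) or orthoE replicate 3 (adjusted p = 0.065). SLC4A1 (0.35 ± 0.27, adjusted p = 0.31, and −0.88 by library size) did not pass. The edgeR quasi-likelihood test called 6886 genes, 3123 higher and 3763 lower in orthoE, 5228 of them by at least 2-fold, with 7924 at an unadjusted p under 0.05. By library size 770 were higher and 8338 lower, but by RLE 3990 and 3043, and by DESeq2 4298 and 3222. Replicates 2 and 3 alone gave 6538.

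Division lists shifted downward from polyE to orthoE. Of 38 mitosis genes, 0 rose and 37 fell, with the same counts adjusted over the list alone and 0 and 38 by library size. The mitosis list had a median log2 fold change of −2.31, adjusted p = 6.3e-12, and adjusted p = 0.62 with an estimated correlation. Of 41 DNA replication genes, 0 rose and 36 fell, with 0 and 37 adjusted over the list alone and 0 and 41 by library size. The replication list had a median log2 fold change of −2.33, adjusted p = 1.5e-13, and adjusted p = 0.48 with an estimated correlation. Of 31 nuclear export and import genes, 6 rose and 23 fell, with 6 and 24 adjusted over the list alone and 1 and 25 by library size. The nuclear transport list had a median log2 fold change of −1.40, adjusted p = 0.00011, and adjusted p = 0.48 with an estimated correlation. Of 35 chromatin condensation and enucleation genes, 8 rose and 20 fell, with the same counts adjusted over the list alone and 4 and 27 by library size. The chromatin list had a median log2 fold change of −1.21, adjusted p = 0.025, and adjusted p = 0.69 with an estimated correlation. Of 70 ribosomal protein genes, 0 rose and 37 fell, with the same counts adjusted over the list alone and 0 and 69 by library size. The ribosomal protein list had a median log2 fold change of −0.63, adjusted p = 0.00011, and adjusted p = 0.76 with an estimated correlation. With uniquely mapped counts that list pointed up and did not pass (adjusted p = 0.53). Of 30 genes of the ubiquitin system, 22 rose and 2 fell, with 22 and 3 adjusted over the list alone and 11 and 10 by library size. The ubiquitin list had a median log2 fold change of 1.51 (0.28 by library size), adjusted p = 3.1e-06, and adjusted p = 0.48 with an estimated correlation. RNF10 rose 6.07-fold and UBXN6 4.95-fold. Of 31 autophagy and mitophagy genes, 20 rose and 6 fell, with 21 and 6 adjusted over the list alone and 10 and 11 by library size. The autophagy list had a median log2 fold change of 1.08 (−0.15 by library size), adjusted p = 0.00046, and adjusted p = 0.48 with an estimated correlation. Of 11 globin and globin chaperone genes, 7 rose and 0 fell, with 7 and 1 adjusted over the list alone and 4 and 2 by library size. The globin list had a median log2 fold change of 1.68 (0.41 by library size), adjusted p = 0.0032, and adjusted p = 0.48 with an estimated correlation. Of 37 red cell membrane genes, 13 rose and 5 fell, with the same counts adjusted over the list alone and 2 and 24 by library size. The membrane list had a median log2 fold change of 0.15 (−1.09 by library size), adjusted p = 0.20. By TMM, 2 of the 4 marker lists of other cell types passed, upward. Of 12 megakaryocyte and platelet markers, 7 rose and 0 fell, with 11 and 1 adjusted over the list alone and 0 and 1 by library size. The megakaryocyte list had a median log2 fold change of 2.07 (0.92 by library size), adjusted p = 0.0048, and adjusted p = 0.62 with an estimated correlation. Of 14 monocyte and macrophage markers, 7 rose and 0 fell, with the same counts adjusted over the list alone and 1 and 0 by library size. The monocyte list had a median log2 fold change of 1.87 (0.75 by library size), adjusted p = 0.0032, and adjusted p = 0.68 with an estimated correlation. Of 11 granulocyte markers, 1 rose and 0 fell, with 0 and 0 adjusted over the list alone and 0 and 1 by library size. The granulocyte list had a median log2 fold change of 1.81 (0.72 by library size), adjusted p = 0.30. Of 9 mast cell, eosinophil and basophil markers, 1 rose and 0 fell, with the same counts adjusted over the list alone and 0 and 1 by library size. The mast cell list had a median log2 fold change of 1.43 (0.23 by library size), adjusted p = 0.37. In all, 14 lists were called, and none with an estimated correlation.

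Transcript usage, the shares of a gene's counts on its transcripts, was tested in 6948 genes with edgeR's diffSpliceDGE. For orthoE against proE 1536 genes passed (2347 at an unadjusted p under 0.05), and for orthoE against polyE 594 (1431 unadjusted). Their most changed share, adjusted for effective length, moved by 20 points or more without overlap between stages in 1152 and 307. Genes were named by it, but shares quoted are of counts (APEX2 12.3 points, not 41.8, and UBE2N 61.9, not 45.6, in orthoE against proE). In LDHB, a lactate dehydrogenase gene, 1 coding transcript held 0.215% ± 0.372 in orthoE against 30.3% ± 4.31 in proE (SD, n = 3) of the gene's counts (adjusted p = 3.7e-10 for the transcript and 9.7e-14 for the gene). A coding transcript of the nuclear import gene TNPO2 held 0.876% ± 0.326 in orthoE against 37.5% ± 4.56 in proE (SD, n = 3). For UBE2N, a coding transcript held 74.9% ± 5.50 in orthoE against 13.0% ± 3.01 in proE (SD, n = 3), and for HBG2, a near-identical copy of HBG1, 97.2% ± 2.09 in orthoE against 0.271% ± 0.0859 in proE (SD, n = 3). NFIA, APEX2, PAK1 and SNX22 completed the 8 genes chosen for orthoE against proE (adjusted p from 9.7e-14 to 2.1e-09). For orthoE against polyE they were NFIA, SNX22, APEX2, UBE2N, AURKAIP1, GSTO1, NEDD4 and RPLP0 (adjusted p from 1.8e-10 to 3.2e-06), with a coding transcript of NFIA at 0% ± 0 in orthoE against 29.8% ± 2.62 in polyE (SD, n = 3). EPB41, whose splicing is developmentally regulated, did not pass for orthoE against proE (adjusted p = 0.75) or orthoE against polyE (adjusted p = 0.22), though with uniquely mapped counts it passed for orthoE against proE. Most of these shares rest on reads split between transcripts. Uniquely mapped reads of the LDHB and SNX22 transcripts tested and of those TNPO2 and NFIA transcripts numbered 0. Those of APEX2 lay on its coding transcript in both stages, all in orthoE and 99.96% in proE. Those of the UBE2N transcript above went the other way, with 74.6% of the gene's unique reads in orthoE and 83.5% in proE, and so did those of the HBG2 transcript, with 7.88% and 10%. On simulated data, 26.5% and 20.4% of the usage calls in these comparisons were false, so single genes are uncertain. Uniquely mapped counts alone called 452 of 2249 genes for orthoE against proE and 62 for orthoE against polyE, and of 526 genes called with estimated counts and testable here, 168 were called again.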

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

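The tests of explanations for the FPKM pattern in this part were chosen after the result was seen, while the share of FPKM itself had been chosen before the data were examined.

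The globin share of the deposited FPKM fell from proE to orthoE although the globin share of counts rose. The orthoE minus proE difference was -3.49 percentage points by FPKM, and it drew attention because FPKM was not used in any comparison. Less globin RNA in orthoE is argued against by uniquely mapped reads, whose globin share was higher in orthoE by 9.45 points, beyond the SD of either stage. Very short effective lengths of other transcripts, which inflate their FPKM, are argued against as the cause: without transcripts of effective length under 50 bases the difference was still -4.30 points. What remains is the effective length of the globin transcripts themselves. In orthoE eXpress gave HBA1 a median effective length 405 times, HBA2 438 times and HBB 6.12 times the annotated length, against 0.854, 0.742 and 0.881 times in proE. With annotated lengths in place of effective lengths the difference was 54.6 points, so the effective lengths may account for the fall. Globin FPKM of late stages are therefore no measure of globin RNA here.

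Transcripts without a gene in the annotation were left out of the comparisons, and they held up to 13.5% of a library's estimated counts, in a proE library. In orthoE replicate 3, 3.40% of estimated counts lay in transcripts shorter than 300 bases without a gene, against 0.228% to 0.788% in the other 14 libraries, and 21.99% of its uniquely mapped counts had no gene. This signal lies outside the tested genes, no explanation for it was tested, and the counts of changed genes without that library were 10543 for orthoE against proE and 6360 for orthoE against polyE.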

How the results depend on the processing

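Replicates 2 and 3 alone and the read-through gene as globin were chosen after the result was seen, the others before the data were examined. Where a value moved, the cause was not tested unless the setting's own construction shows it.

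The large gene counts moved by less than 1.5-fold under RLE size factors, library size, globin removal, no filter, the replicate block, DESeq2, the 2 stages alone and replicates 2 and 3 alone. Leaving out a library gave 11316 to 11824 genes over the 5 stages, 10489 to 10811 for orthoE against proE, 6215 to 6692 for polyE against lateBasoE and 6145 to 6961 for orthoE against polyE. By RLE and DESeq2 most orthoE against polyE calls were higher, not lower. The small counts moved most. For earlyBasoE against proE, 11 in the report, the count was 23 with no filter, 99 with the replicate block, 169 with DESeq2 (1091 at an unadjusted p under 0.05), 1 with the 2 stages alone, and 1 to 20 with a library left out. For lateBasoE against earlyBasoE, 254 in the report, it was 447 by library size, 138 with no filter, 1439 with the replicate block, 1117 with DESeq2, 672 with the 2 stages alone, 422 in replicates 2 and 3 alone, and 0 to 186 with a library left out.

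Uniquely mapped counts, which hold fewer reads and test fewer genes, gave 7147 genes for orthoE against proE, 5 for earlyBasoE against proE, 83 for lateBasoE against earlyBasoE, 4408 for polyE against lateBasoE, 4072 for orthoE against polyE and 7584 over the 5 stages, and 6651, 4, 64, 4072, 3663 and 7231 of these were also in the main results. They called 12 lists for earlyBasoE against proE, against 20. Usage calls were 452 for orthoE against proE and 62 against polyE, of which 168 and 13 were among the main calls. With limma's diffSplice on voom values, usage calls for orthoE against polyE were 391, 258 of them shared. Leaving out a library gave 1252 to 1669 and 494 to 833 usage calls.

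With an estimated correlation camera called 0 lists for orthoE against proE, 0 for earlyBasoE against proE, 3 for lateBasoE against earlyBasoE, 1 for polyE against lateBasoE and 0 for orthoE against polyE. Fry, which does not compare a list with other genes, called 27, 1, 12, 24 and 21 in the same order, all 21 main calls for orthoE against proE among the 27. Leaving out a library gave 19 to 22, 16 to 20, 15 to 18, 20 to 23 and 13 to 15 lists. Some lists reversed direction: for orthoE against proE, chromatin condensation (adjusted p = 0.651 with uniquely mapped counts and 0.184 with fry), glycolysis (0.525 with uniquely mapped counts), nonsense-mediated decay (0.538 with fry and 0.842 in replicates 2 and 3) and splicing factors (0.0941 with uniquely mapped counts), and for orthoE against polyE ribosomal proteins (0.526 with uniquely mapped counts), a called list.

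The rise of the globin share from proE to orthoE, 39.0 points, was 37.9 to 39.9 with a library left out, 44.3 with the read-through gene and 9.45 by uniquely mapped counts, which leave out reads shared by near-identical globin genes. It was -3.49 by FPKM.

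By library size alone 6 of 147 results for named genes changed sign: log2 -1.03 for GATA1, -1.03 for SF3B1 and -1.97 for TFRC in orthoE against proE, -0.12 for TFRC in polyE against lateBasoE, and -0.60 for KLF1 and -0.88 for SLC4A1 in orthoE against polyE. With RLE size factors 143 of 147 kept direction and side of the threshold, with no filter 142, with the replicate block 145, with DESeq2 142, with the 2 stages alone 137, in replicates 2 and 3 alone 141, with globin genes removed all 138 that could be tested, and with uniquely mapped counts 116 of 134. Of 882 values with a library left out, 757 did, and 109 of the other 125 were in lateBasoE against earlyBasoE. On simulated data in which few genes changed, 2-fold changes were recovered in 6% to 20% of genes between 2 stages.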

Other observations

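The transcript-usage, retained-intron and split tests in this part were chosen after the result was seen, and the scaling tests after the pattern but before their own result was seen.

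Most genes lay lower in orthoE than in proE by library size, with a median log2 fold change of -2.69, and not by TMM, with -0.32. Globin genes taking the counts are argued against as the whole cause: with the 10 globin genes removed and not the chaperone gene of the globin list, 45.7% of the orthoE counts of tested genes, the TMM factors still differed by 1.55 on the log2 scale, against 2.38 before. With the 100 most abundant orthoE genes removed, 70.1% of counts, 0.738 remained, but genes picked for being high in orthoE lower the difference by construction, so this does not decide. A wider set of abundant messages may add to the globin share, and a loss of total RNA per cell stays open, since no measure of RNA per cell is in these data.

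Transcript shares moved between proE and orthoE in 1536 genes. Of the 1166 genes with any length-adjusted share moved by 20 points or more, 621 had a moving transcript without uniquely mapped reads in either stage. In 216 of the 1166, with at least 20 such reads in each stage and for each of the 2 transcripts, these reads moved the same way as the estimated counts in 196, or 90.7%, and among 75 genes called with both kinds of count and with as many reads in 72, or 96%. The estimated counts contain the unique reads, and the second set was picked for its unique counts, so these matches are in part built in and decide nothing. Stage-dependent use of transcripts and division of shared reads by eXpress may each play a part, and both stay open.

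That introns are retained in late erythroblasts is general knowledge from outside these sources, and these tables allow a look. In the median gene, retained-intron transcripts held 3.09% ± 1.14 (SD, n = 3) of estimated counts in proE and 4.61% ± 0.285 (SD, n = 3) in orthoE, a difference of 1.52 points with globin genes left out, which was 0.884 without proE replicate 2 and up to 1.98 without another library. By uniquely mapped counts the values were 1.82% ± 0.607 and 4.21% ± 0.785 (SD, n = 3). A rise of such transcripts is likely small, and a retained intron cannot be told from unspliced precursor RNA here.

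Other splits of the same libraries were run for each count. Over the 5 stages, 1 of 100 splits, the real one, gave as many as 11539 genes, and the highest other gave 3510. For 2 stages, 6 libraries make 10 splits, too few for a share under 0.05, and only the values are given. For orthoE against proE 1 split gave as many as 10842 genes and the highest other gave 0. For earlyBasoE against proE 1 gave 11, and the highest other 1, or 0 among splits that part as many pairs of replicate numbers. For lateBasoE against earlyBasoE 1 gave 254 and the highest other 0, and for polyE against lateBasoE 1 gave 7196 and the highest other 0. For orthoE against polyE 1 gave 6886 and the highest other 10. Lists were called almost as often in other splits: 21 against at most 20 for orthoE against proE (1 split as high), 20 against 18 for earlyBasoE against proE (1), 17 against 17 for lateBasoE against earlyBasoE (2), 21 against 18 for polyE against lateBasoE (1) and 14 against 15 for orthoE against polyE (2). Each other split of 2 stages put 2 libraries of 1 stage with 1 of the other. Part of the stage difference then stayed between the groups and part entered the spread. Such splits do not show the calls without a difference, so they decide nothing about lists, and low gene and usage counts are partly built in. List calls at the preset correlation still rest on that setting, as few held with an estimated one. For usage, 1 split gave 1536 genes for orthoE against proE and the highest other 11, and 1 gave 594 for orthoE against polyE and the highest other 169.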
